A study of Mus musculus with 10 samples.

How the data were processed

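Kidney RNA from 10 mice was measured on Affymetrix MG_U74Av2 arrays, 1 array per animal, with 5 mice carrying an FGF23 transgene (TG) and 5 wild-type littermates (WT), collected at 8 weeks of age. The transgene is human FGF23 behind a collagen promoter, per the labels, so mouse Fgf23 on the array would not report it. Groups were taken from the sample titles, because the genotype field of the labels reads transgenic for all 10 samples, wild-type animals included. Animals are named by group and animal number. Pairing of littermates, the sex of the animals and the time of day at collection were not given in the sources used here. The labels give 6 ug of RNA per sample.

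The deposited table holds 1 log2 value per probe set and array, made by GCRMA per the submitters' processing notes, which give no version. That the values are on the log2 scale was read from their range. Values were used as deposited, and the probe-level image files were not used. Chip type, chip lot, fluidics station and the order of the processing days came from the array run records, per the file headers. Of 12488 probe sets, 66 are controls and were left out, 10855 name 1 gene, 396 name several genes and 1193 name none. Gene symbols were looked up in the reference table of gene names: 0 were replaced by a newer symbol and 16 found no match and were kept as written. The number of arrays limits the precision.

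A probe set was tested when its log2 value was over 4 on at least 5 of the 10 arrays, whichever arrays these were. This left 6814 probe sets for 5295 genes and left out 5608. TG was compared with WT by limma 3.58.1 in R 4.3.3, with lmFit and eBayes, no trend and no robust option, as a two-sided moderated test with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05 on the adjusted p. Each gene was represented by its probe set with the highest mean over all 10 arrays among those that name 1 gene. Of 762 genes with several tested probe sets, 0 had probe sets past the threshold in opposite directions. With 83 of 6814 probe sets past the threshold, few genes could have shown this, so it says little about how far probe sets of a gene match. Errors of log2 differences are standard errors from limma, and errors of group means are SD with n = 5 per group.

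There were 32 gene lists, covering kidney segments, transport, signalling, metabolism, stress and other cell types or tissues. The 27 lists with at least 5 tested genes were tested by limma's camera with a preset correlation of 0.01 between genes, two-sided and adjusted over the lists, and again with an estimated correlation and with fry. The remaining 5 lists were too small. Counts adjusted over the list alone are given beside counts adjusted over all probe sets. Exact permutation tests between TG and WT ran over all 252 assignments of 10 animals to groups of 5, where the smallest two-sided p is 0.00794. For the gap of a list between animal number ranges, the range was permuted within each genotype, over 100 assignments. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

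The comparison, its test and filter, the gene lists, the focus genes of the FGF23, phosphate and vitamin D axis, the rule for naming genes and most alternatives were chosen before the data were examined. The rule names every focus gene, the 12 largest rises and 12 largest falls among genes past the threshold, in each list whose members are described up to 4 members past the threshold or otherwise the 2 with the smallest p, and Xist with the Y-linked genes as a check of sex. Which 16 lists have their members described was decided after the values were seen, in part so that fewer near-zero values were printed. The other 16 lists are given by their counts and tests. Adipoq, Apob, some list members that passed only with sex in the model (Xpr1, Slc22a6, Slc22a12, Slc17a1, Car4, Ace, Slc2a1 and Btg2), the probe sets without a gene name, the liver markers and the clock genes lie outside the rule and were chosen after their values were seen. Where most or all animals of a group lay under the log2 value of 4, the floor, the difference with values under the floor set to it is given too, also chosen afterwards.

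Sex was read from Xist, with female set at a log2 value over 6, and checked against the Y-linked Eif2s3y. Alternatives set before the data were examined covered no filter, a filter at log2 over 6, trended and robust variances, array weights, quantile normalization, median centring, log2 of the linear value plus 16, chip lot, fluidics station, processing day, animal number range (612 to 619 against 650 to 663) and sex in the model, the mean of a gene's probe sets, an exact permutation test, a threshold of 0.01, a threshold of 2-fold, and leaving out each animal in turn. Added after the data were seen were sex with number range, the difference between the actin 3' and 5' control probe sets as a covariate, males alone, females alone, and the arrays of the first day alone.

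The steps were tested on simulated data of the same size as the TG and WT comparison, 6814 probe sets in 10 simulations with 200 changed in each. Of changed probe sets, 55.4% were recovered at 1.5-fold, 88.8% at 2-fold and 98.3% at 4-fold, and 4.96% of the calls were unchanged probe sets. With every member raised by 0.5 on the log2 scale, camera called 95.0% of lists, and it called 0% of lists free of raised members. The simulated genes were independent of each other, which measured genes are not.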

Results

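Expression in whole kidney was measured on 10 arrays from 5 FGF23 transgenic mice (TG 614, 619, 652, 657 and 661) and 5 wild-type littermates (WT 612, 618, 650, 658 and 663). FGF23 is the hormone by which bone lowers phosphate reabsorption and active vitamin D in the kidney. The comparison asks which kidney transcripts differ between mice with an FGF23 transgene and their littermates. Between 53.0% and 57.0% of the probe sets lay over the floor on each array, and the correlation between arrays ran from 0.946 to 0.993. The floor is the log2 value of 4 chosen for the filter, not a measured limit of detection. Xist and Eif2s3y showed 2 females and 3 males in each group: Xist was 9.94 to 11.90 in females and 3.09 to 3.36 in males, and Eif2s3y 3.88 to 4.43 and 8.06 to 8.53. The other measured Y-linked genes, Kdm5d and Uty, read at most 4.05 and 4.16 on any array and were not tested. The females were WT 612, WT 650, TG 614 and TG 652.

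Klotho (Kl, probe set 100956_at), the co-receptor through which FGF23 acts on the tubule, was 1.69-fold lower in TG kidneys, at 11.48 ± 0.06 against 12.24 ± 0.07 (log2, SD, n = 5), and every TG value lay below every WT value. The scaffold protein gene Pdzk1, whose product binds the phosphate cotransporter at the brush border, fell by 0.47 ± 0.09 (log2 difference, SE, adjusted p = 0.037). Pdzk1 passed in 2 of the 10 fits with 1 animal left out, and its other probe set differed by -0.17. Of 12 tested tubular injury transcripts 4 rose, among them the lipocalin Lcn2 (9.56-fold higher) and clusterin (Clu, 3.04-fold higher). For that list camera gave adjusted p = 3.54e-06, and adjusted p = 0.107 with an estimated correlation. Dnase1, the secreted deoxyribonuclease made in the kidney, was 9.82-fold lower, at 8.53 ± 0.66 against 11.83 ± 0.48. In all, 83 of 6814 probe sets passed the test, 54 higher and 29 lower in TG.

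**Figure D1:**
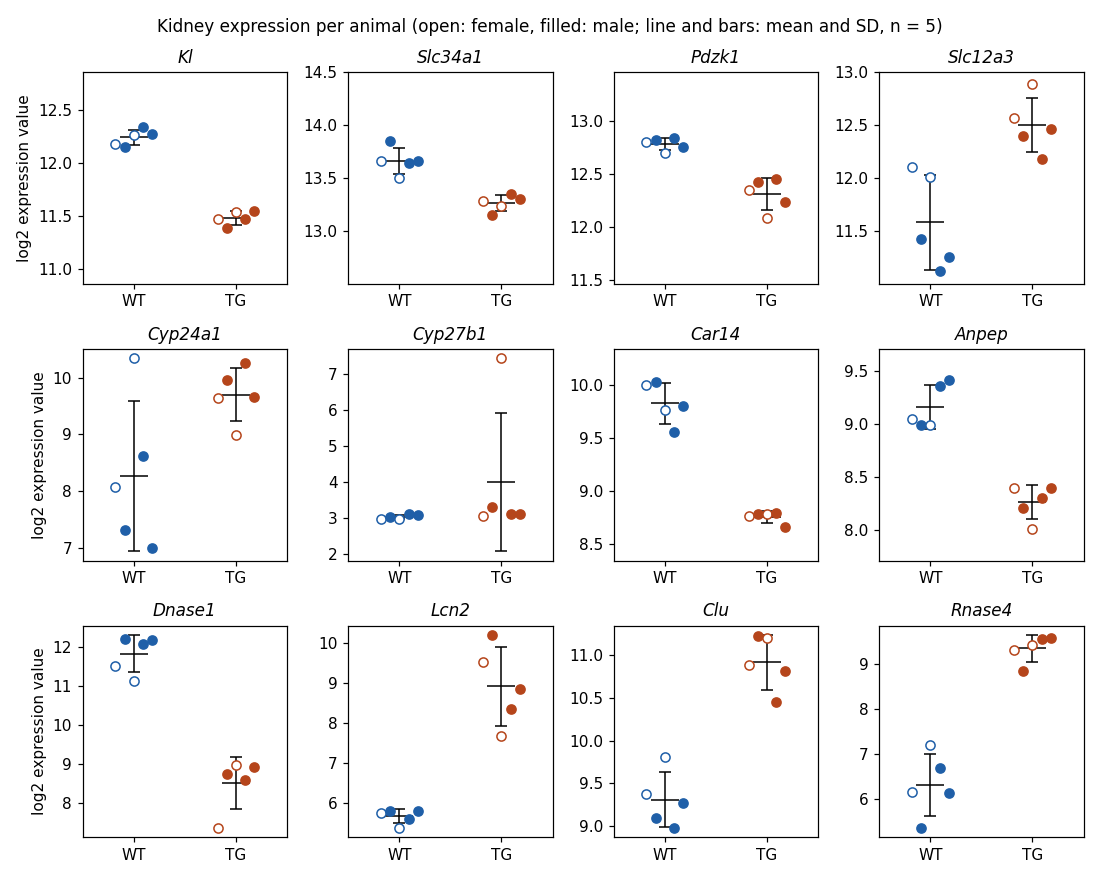
Log2 expression values of 12 genes per animal (y axis) in WT and TG kidneys (x axis), open circles for females and filled for males, with the mean and SD of the 5 animals of each group. Apart from Cyp24a1 and Cyp27b1, the genes show no overlap between the groups, and Cyp27b1 stands out in TG 652 at 7.44.

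Among the 13 focus genes of the FGF23, phosphate and vitamin D axis, 9 were tested, 1 passed, and 5 passed when adjusted over the list alone. Kl fell by 0.76 ± 0.07 (adjusted p = 0.000897). Slc34a1, the main sodium-phosphate cotransporter of the proximal tubule, differed by -0.40 ± 0.08 (adjusted p = 0.0533), and Slc12a3, the thiazide-sensitive sodium-chloride cotransporter of the distal convoluted tubule, by 0.92 ± 0.21 (adjusted p = 0.0722). With sex in the model both passed, at adjusted p = 0.0258 for Slc34a1 and 0.00328 for Slc12a3. Cyp24a1, which inactivates vitamin D, differed by 1.43 ± 0.54 (adjusted p = 0.308), by 0.10 in females and 2.31 in males (adjusted p of that difference = 0.996), and without WT 650, where it stood at 10.34, its adjusted p was 0.0365. Cyp27b1, which makes the active form of vitamin D, lay under the floor on every array except that of TG 652 at 7.44 and was not tested. The differences for Vdr (0.14 ± 0.12), Pth1r (-0.58 ± 0.20), Fgfr1 (0.09 ± 0.17), Egr1 (-0.34 ± 0.65) and Calb1 (-0.58 ± 0.25) did not pass. No probe set names Slc34a3, Trpv5 or Fgf23 alone.

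Of the 9 tested genes of the phosphate transport list, 1 fell, 0 rose and 8 did not pass, with 6 lower when adjusted over the list alone. The member that fell was Pdzk1 (adjusted p = 0.037), which passed in 2 of the 10 fits with 1 animal left out, while its other probe set differed by -0.17, and the list's median was -0.41. With sex in the model 3 members fell, Pdzk1, Slc34a1 and the phosphate exporter Xpr1 (-0.51, adjusted p = 0.0148). The list was called lower by camera (adjusted p = 0.000145), and with an estimated correlation the adjusted p was 0.107. The 18 tested solute transporters of the proximal tubule held 0 genes that passed, 0 also when adjusted over the list alone, with a median of -0.30. Of these, 3 fell with sex in the model: the organic anion transporter Slc22a6 by 0.83 (adjusted p = 0.0352), the urate transporter Slc22a12 by 0.71 (adjusted p = 0.0411) and Slc17a1 by 0.41 (adjusted p = 0.0261). In the model without sex, the glucose transporter Slc2a2 differed by -0.54 ± 0.15 and the bicarbonate cotransporter Slc4a4 by -0.51 ± 0.20. Camera called this list lower (adjusted p = 0.0248, and adjusted p = 0.576 with an estimated correlation). That call was lost with quantile normalization and without TG 614, TG 619, WT 650 or WT 658, with adjusted p up to 0.126. In the gluconeogenesis and ammonia production list, 1 of 13 genes fell, 0 rose, 12 did not pass, and 2 passed when adjusted over the list alone, 1 higher and 1 lower. Its fallen member was Car14, a membrane-bound carbonic anhydrase (-1.07 ± 0.10, adjusted p = 0.000897), and with sex in the model Car4 fell too, by 0.81 (adjusted p = 0.0391). The other probe set of Car4 differed by -0.37. This list too was called lower by camera (adjusted p = 0.0151, and adjusted p = 0.37 with an estimated correlation), a call lost with quantile normalization and without TG 619 or WT 650, with adjusted p up to 0.0744. In the renin-angiotensin list, 1 of 6 genes fell, 0 rose and 5 did not pass, and 1 passed when adjusted over the list alone. It was Anpep, the brush-border aminopeptidase N (-0.90 ± 0.12, adjusted p = 0.00636), and camera gave adjusted p = 0.748. Ace fell as well with sex in the model, by 0.86 (adjusted p = 0.0124), while its other probe set differed by -0.20.

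Markers of the thick ascending limb and distal convoluted tubule lay mostly higher in TG: 8 of 10 tested genes had a positive difference, 0 passed, and 2 passed when adjusted over the list alone. Their median was 0.49, and the examples with the smallest p were Slc12a3 and the potassium channel gene Kcnj1 (0.78 ± 0.21), which both rose with sex in the model (adjusted p = 0.00328 and 0.0119). Pvalb and Calb1, also in this list, went the other way, at -0.91 ± 0.40 and -0.58 ± 0.25. Camera called the list higher (adjusted p = 0.0101, and adjusted p = 0.615 with an estimated correlation), and lost that call in females alone and without TG 652, with adjusted p up to 0.101. The sodium and potassium transport list, led by the same pair of genes, had 0 of 9 genes past the test, 2 when adjusted over the list alone, and a median of 0.32. Camera called it higher (adjusted p = 0.00431, and adjusted p = 0.414 with an estimated correlation). Of 4 tested intercalated cell markers, 2 rose, 0 fell and 2 did not pass, with 3 when adjusted over the list alone. The receptor gene Kit rose by 1.30 ± 0.26 (adjusted p = 0.044) and the anion exchanger gene Slc4a1 by 0.83 ± 0.17 (adjusted p = 0.0478), and the list was too small for camera. Collecting duct principal cell markers held 0 of 5 genes past the test and 2 when adjusted over the list alone, with opposite signs: the water channel gene Aqp4 at -1.18 ± 0.34 (adjusted p = 0.022 with sex in the model) and Hsd11b2 at 0.47 ± 0.17. Camera gave adjusted p = 0.67, with a median of 0.26 and a mean of -0.01. Of 5 distal calcium and magnesium genes 0 passed, 0 also when adjusted over the list alone, with Pvalb at -0.91 ± 0.40 and Calb1 the examples. Camera gave adjusted p = 0.937 with a lower direction, where the median was 0.16 and the mean -0.11.

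In the tubular injury list 4 of 12 tested genes rose, 0 fell and 8 did not pass, and 5 passed when adjusted over the list alone. Lcn2 rose by 3.26 ± 0.39 (adjusted p = 0.00388), Clu by 1.61 ± 0.19 (adjusted p = 0.00322), the fibrinogen chain gene Fgg by 1.72 ± 0.22 (adjusted p = 0.00599) and the galectin gene Lgals3 by 0.96 ± 0.16 (adjusted p = 0.0184). Fgb, another fibrinogen chain gene of this list, differed by 0.06 ± 0.14 (adjusted p = 0.889). Fgg is also counted further below among the transcripts known as abundant in liver. By camera the list was called higher (adjusted p = 3.54e-06, and adjusted p = 0.107 with an estimated correlation). All 16 tested leukocyte markers had a positive difference, with a median of 0.94: 2 rose, 0 fell, 14 did not pass, and 10 passed when adjusted over the list alone. The genes that rose were the lysosomal protease Ctss (1.24 ± 0.23, adjusted p = 0.037) and the complement gene C1qa (1.46 ± 0.31, adjusted p = 0.0493), and with sex in the model 6 rose. Camera called the list higher (adjusted p = 2.77e-10, and adjusted p = 0.399 with an estimated correlation). The mean difference of this list was 0.44 in the animals numbered 650 to 663 and larger by 1.06 in those numbered 612 to 619, a gap with exact two-sided permutation p = 0.02, or 0.18 adjusted over 9 lists, in a test chosen after the values were seen. Of 28 extracellular matrix genes 0 passed, 2 passed when adjusted over the list alone, and 24 lay higher, with the collagen Col5a2 at 1.46 ± 0.35 (adjusted p = 0.0473 with sex in the model) and Tgfbi at 0.77 ± 0.19. Camera called the list higher (adjusted p = 0.000102, and adjusted p = 0.615 with an estimated correlation), with mean differences of 0.85 and 0.06 in the lower and higher number range (exact two-sided permutation p of the gap = 0.1). Of 16 interferon response genes 0 passed, 0 also when adjusted over the list alone, and 14 lay higher, with the guanylate-binding protein gene Gbp2 at 0.97 ± 0.30 (adjusted p = 0.039 with sex in the model) and the related GTPase gene Irgm1 at 0.43 ± 0.15. The interferon list was called higher (adjusted p = 2.81e-05, and adjusted p = 0.414 with an estimated correlation).

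**Figure D2:**
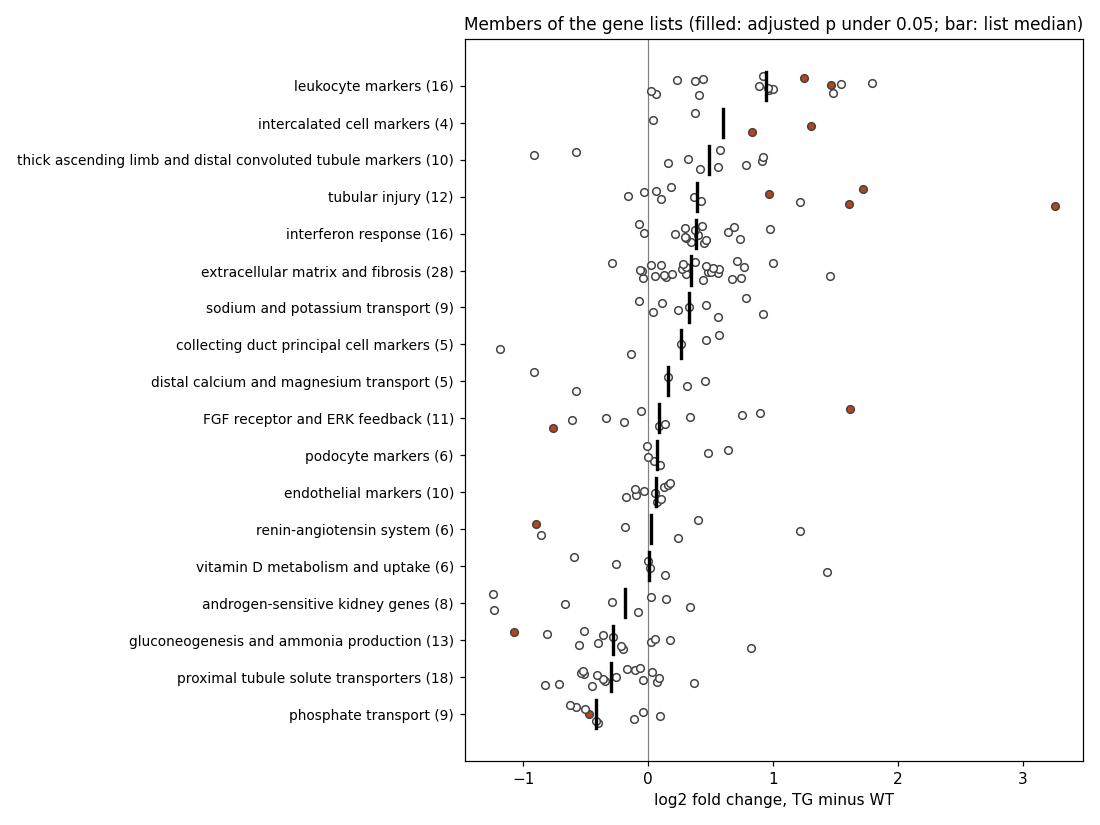
Log2 fold change of TG minus WT (x axis) of each tested member of 18 gene lists (y axis, number tested in brackets), 1 point per gene, filled where the adjusted p passed the threshold, with a bar at the list median. The leukocyte median lies at 0.94 and the phosphate transport median at -0.41.

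The FGF receptor and ERK feedback list had Kl fallen, Ier3 risen and 9 of 11 genes not passing, with 5 when adjusted over the list alone, a median of 0.09 and camera adjusted p = 0.797. Ier3, a stress-responsive early gene, rose by 1.62 ± 0.24 (adjusted p = 0.012). In the list of vitamin D metabolism and uptake 0 of 6 genes passed and 1 when adjusted over the list alone, Lrpap1, the chaperone of megalin, at -0.59 ± 0.13 (adjusted p = 0.0343 with sex in the model). Camera gave adjusted p = 0.925 with a lower direction, where the median was 0.01 and the mean 0.12. Among 8 androgen-sensitive kidney genes 0 passed, 0 also when adjusted over the list alone, with Odc1 at -1.23 ± 0.47 and Cyp2e1 at -0.67 ± 0.76, and camera gave adjusted p = 0.569. Odc1, with sex in the model, fell by 1.23 ± 0.22 (adjusted p = 0.0141), at -0.55 in females and -1.69 in males (adjusted p of that difference = 0.996).

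The largest rises among named genes included several transcripts known for high expression in liver, a grouping made after the values were seen. As a set, 13 other liver transcripts had a median difference of -0.041, with 4 of them over the floor. Fabp1, the liver-type fatty acid binding protein, rose by 4.88 ± 1.00 (adjusted p = 0.0478), with TG 661 at 5.96 and the other TG animals at 10.88 to 11.47, and of the 10 fits with 1 animal left out it passed in 1, that without TG 661. The thyroxine carrier Ttr rose by 3.89 ± 0.72 (adjusted p = 0.037) and the apolipoprotein Apoc1 by 2.96 ± 0.45 (adjusted p = 0.0123), or by 2.71 with values under the floor of 4 set to it, as 4 of 5 WT animals lay there, while Apob, named after its values were seen, rose by 0.93 ± 0.18 (adjusted p = 0.0454). The secreted ribonuclease Rnase4 rose by 3.05 ± 0.30. Its relative Ang, under the floor in all 5 WT animals, rose by at least 1.55 against the floor (adjusted p = 0.00969 on the values as deposited). The phosphatase gene Dusp9 rose by 2.29 ± 0.29, its other probe set differing by -0.09. The protease gene Ctsc rose by 1.77 ± 0.29, with its other probe sets at 1.52 and -0.05. The granzyme inhibitor Serpinb9 (1.86 ± 0.37) and the prostaglandin E synthase Ptges (1.66 ± 0.24) rose as well. Probe set 99481_at, which names no gene, had the largest difference of all, 5.62 ± 0.37 (adjusted p = 9.09e-05), at 8.93 to 10.70 in TG and 3.72 to 4.76 in WT. With 2 WT animals set to the floor the difference was 5.52. Its probe sequences were not among the sources used here, so whether it detects the transgene's own RNA is not known.

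The falls were fewer and mostly smaller. Car3, a carbonic anhydrase of muscle and fat, fell by 3.33 ± 0.52 (adjusted p = 0.0147) and Dnase1 by 3.30 ± 0.32 (adjusted p = 0.000897). Car3 stood highest in WT 650 at 9.54, the animal in which the fat marker Adipoq read 8.17 against 3.07 to 4.91 elsewhere, and it also passed without that animal. The neurotrophin Bdnf fell by 1.08 ± 0.16, Ankrd33b by 0.98 ± 0.16, and the glycerol phosphate dehydrogenase Gpd1 by 0.76 ± 0.15. The convertase Pcsk5 was under the floor in all 5 TG animals and lower by at least 0.43 against the floor (adjusted p = 0.0404 on the values as deposited). The creatine synthesis gene Gamt fell by 0.75 ± 0.15, the tyrosine kinase Ptk2b by 0.71 ± 0.15 and the elongation factor Tcea3 by 0.70 ± 0.14. Probe set 160986_r_at, with no gene name, fell by 1.26 ± 0.12 (adjusted p = 0.000897).

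Markers of other cell types and tissues gave few differences. Of 10 endothelial and 6 podocyte markers 0 passed, with medians of 0.06 and 0.07 and camera adjusted p of 0.925 and 0.38. Blood markers were too few for camera, and 1 of 3 tested rose, the red cell anion exchanger Slc4a1 that also marks intercalated cells, while the haemoglobin gene Hba-a1 differed by 0.20. Of 5 adipose markers 0 passed and 0 lay higher in TG, with a median of -0.20 and camera adjusted p = 0.109. Camera did call the adipose list with no filter, with day as block, in females alone, on the first day alone and without WT 618 or WT 663. Whether fat in the samples bears on the fall of Car3 was not tested. Pvalb was the 1 skeletal muscle marker tested, Eif2s3y (-0.05) the 1 sex-linked gene, and 0 adrenal markers were over the floor. Fatty acid oxidation (22 tested, median -0.14, camera adjusted p = 0.171), oxidative phosphorylation (31, -0.03, 0.348), mineralization and bone matrix (8, -0.19, 0.493), cell cycle (12, 0.08, 0.748), circadian clock (11, median near 0, 0.932) and oxidative stress genes (19, -0.06, 0.67) had 0 members past the test. Cholesterol synthesis (15 tested, adjusted p = 0.937) had a median of -0.05 and a mean of -0.01 with a higher camera direction, and hypoxia genes (12 tested, adjusted p = 0.932) a median of -0.06 and a mean of 0.05, each with 0 members past the test. The hypoxia gene Slc2a1 rose by 0.72 with sex in the model (adjusted p = 0.0368). Among 15 immediate early and heat shock genes Ier3 alone rose, with a median of -0.09, a mean of 0.13 and camera adjusted p = 0.754, and with sex in the model Btg2 rose too, by 1.02 (adjusted p = 0.0312). Adjusted over the list alone, these lists of other cell types, metabolism and stress had 0 genes past the test except Slc4a1, Ier3 and Pvalb.

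At an unadjusted p under 0.05 there were 868 probe sets, and 81 of the 83 had no overlap between groups, as did 278 of all tested (4.08%, where chance gives 0.794%). The 83 covered 69 genes by their representative probe set, 46 higher and 23 lower, and 39 probe sets were at least 2-fold, 34 of them higher. Camera called 9 of 27 lists, 6 higher and 3 lower, with 0 called with an estimated correlation and 3 by fry: phosphate transport and tubular injury (both adjusted p = 0.00277) and gluconeogenesis and ammonia production (0.0261). With sex in the model 285 probe sets passed, 171 higher and 114 lower, and all 83 were among them. The first processing day held 4 animals of each group, and WT 663 and TG 661 were each alone on a later day. As blocks, chip lot gave 83 probe sets (52 of them among the 83 without a block), station 52 (49), processing day 32 (30) and number range 121 (81). Camera called 9 lists with lot, station or range as block and 11 with day. Kl differed by -0.77 and -0.80 in chip lots 1 and 2, by -0.73 and -0.80 at stations 1 and 2, by -0.77 on the first day and by -0.74 and -0.77 in the lower and higher number range. As a block, lot gave Kl -0.78 (adjusted p = 0.00497), station -0.76 (0.00215), day -0.77 (0.0199) and range -0.76 (0.000746). The third lot held TG 661 alone. Between females and males 978 probe sets differed, in a model with genotype and number range.

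Leaving out 1 animal gave 31 to 92 probe sets: 31 without TG 614, 32 without TG 619, 32 without WT 658, 35 without WT 618, 36 without WT 663, 41 without TG 652, 43 without TG 661 and 45 without TG 657. An exact permutation test per probe set gave 0 after adjustment, with 805 at an exact p under 0.05 and 278 at the smallest p the design allows. That smallest p, 0.00794, is so large for 6814 probe sets that the test could hardly call any.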

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

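The splits of the animals were set up before their results were seen, while the liver, cell share and RNA integrity tests were chosen after.

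Samples far from the rest of their group were looked for in 144 groups of 5 values, and 8 were found where chance gives about 1 in 20, or 7.2. The number after each animal is the gap to the nearest animal as a share of the group's range. Cyp27b1 in TG 652 (0.943) read 7.44 against 3.06 to 3.32 in the other TG animals. Pth1r in TG 652 (0.745) read 10.11 against 10.82 to 11.07. Calb1 in WT 650 (0.711) read 11.73 against 11.04 to 11.24. Fabp1 in TG 661 (0.893) read 5.96 against 10.88 to 11.47. Dnase1 in TG 614 (0.761) read 7.38 against 8.60 to 8.99. Car14 in TG 661 (0.744) read 8.65 against 8.76 to 8.79. Tcea3 in TG 661 (0.809) read 8.22 against 7.54 to 7.67. Slc2a2 in WT 612 (0.71) read 10.35 against 10.84 to 11.04.

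Probe set 93926_at, which names no gene, was the 1 probe set to pass the test for a TG and WT difference that depends on sex, with 283 at an unadjusted p under 0.05. The effect in females minus that in males was -2.99 ± 0.25 (adjusted p = 0.00432). It read 2.49 to 2.78 in WT males, 5.94 to 6.47 in TG males and 8.05 to 8.88 in females of both groups. With the WT males, all 3 under the floor of 4, set to the floor, the gap is -1.60, so the size of -2.99 is not exact.

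For the 83 probe sets, 2 of 100 splits of the 10 arrays into 5 and 5 gave as many, the real one included. A count this high is thus unlikely by chance alone, though chance is not excluded for single probe sets. The other split gave 781 and set all 4 females with TG 619 against the remaining males, which points to a structure of the samples other than genotype. Sex alone is not shown to be that structure, since the 5 splits that set the females with another male gave 0, 0, 1, 0 and 0, and 95 other splits in all gave 0. With sex in the model and 2 females and 3 males kept on each side, 1 of 60 splits, the real one, reached 285, and the highest other gave 1. For the focus genes, 1 of 100 splits reached the real count of 1, and the highest other gave 0, which adds little to the count of probe sets, as 95 splits called no probe set at all. For the 9 lists that camera called, chance stays open: 17 of 100 splits called as many, the highest other 14. With sex in the model 13 of 60 did, the highest other 13.

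For RNA integrity as a cause of the 83, the actin control difference was put in the model, and 345 probe sets followed it. Each of the 83 kept at least 0.833 of its log2 difference. This does not decide on RNA integrity, since the 83 had passed for a small spread within groups. The actin difference varied within groups (SD 0.29 in TG and 0.60 in WT), so a probe set that follows it would seldom have passed. The Gapdh control difference was not put in the model. Of the 83, 38 no longer passed (adjusted p 0.0519 to 0.0905), with a median size of 0.79 before and 0.77 after, while the median SE went from 0.15 to 0.16 and the degrees of freedom from 10.8 to 9.81.

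Fabp1, Ttr, Apoc1, Fgg and Apob, known as abundant in liver, rose by 0.93 to 4.88 in TG kidneys. If 1 share of liver tissue per animal had brought all of them, their rises over the WT mean on the linear scale would go together across the TG animals, but the median r of 10 pairs was -0.103 (SD 0.574), which argues against that. For single genes among the 5 liver tissue cannot be told apart from a change of expression within the kidney under the transgene. The median difference of 13 other liver transcripts was -0.041 (SD over markers 0.29), but 4 of them were over the floor (Alb at 0.90, Apoh at 0.27, Fgb at 0.062 and Hp at -0.21), and with the 5 counted in it was 0.00073 (SD 1.54), so neither decides. A change within the kidney may account for the rises and was not tested further.

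The median difference was 0.94 for leukocyte markers, 0.49 for those of the thick ascending limb and distal convoluted tubule and -0.30 for proximal tubule transporters, and camera called the lists, but not with an estimated correlation (adjusted p = 0.399, 0.615 and 0.576). A lower share of proximal tubule RNA would raise the markers of all other cell types alike, but the difference of leukocyte markers exceeded that of endothelial markers by 0.83 (exact two-sided permutation p = 0.0159, adjusted over 2 tests 0.0317), so it does not account for the leukocyte part. For the thick ascending limb and distal convoluted tubule the gap was 0.29 (exact two-sided permutation p = 0.19, also after adjustment), and a lower proximal share cannot be told apart from a change within those cells. Within that list Pvalb and Calb1 lay lower in TG, but neither passed the test. With the actin control difference in the model, 9 of the 9 lists stayed past the threshold. That difference was 2.14 ± 0.29 in TG and 2.52 ± 0.60 in WT (exact two-sided permutation p = 0.254), and for Gapdh 0.57 ± 0.22 and 0.89 ± 0.37 (exact two-sided permutation p = 0.127). Since other splits of the animals called as many lists, this says little about RNA integrity as a cause of the list calls. More leukocytes, or higher expression in those present, may account for the leukocyte part under the transgene, and chance stays open for the number of lists.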

How the results depend on the processing

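Sex with number range, the actin covariate, single sexes and the first day alone were added after the data were seen, and except where stated the cause of a shift was not tested. The count of 83 probe sets became 48 with no filter, 52 with station, 32 with day, 285 with sex and 549 with sex and number range in the model. Fewer animals were compared in females alone, with 1 (Fabp1), and without the arrays of later days, with 32. The fit with day rests on those same animals, as WT 663 and TG 661 were each alone on their day. With stricter thresholds the count was 39 at 2-fold or more and 18 at an adjusted p under 0.01. Exact permutation gave 0, but it could hardly call any, and its smallest adjusted p is 0.195. Leaving out 1 animal gave 31 to 92: 31 without TG 614, 32 without TG 619, 32 without WT 658, 35 without WT 618, 36 without WT 663, 41 without TG 652, 43 without TG 661 and 45 without TG 657. The 9 lists became 0 with an estimated correlation and 3 by fry, and 7 to 10 with 1 animal left out. The focus count of 1 became 2 at log2 over 6, with trended and robust variance, with log2 of the linear value plus 16, with number range, with the mean of a gene's probe sets and in males alone, 3 with array weights or sex, 4 with sex and number range, and 0 in females alone. With 1 animal left out it was 1 to 4: 2 without WT 612 and 4 without WT 650. Of the 34 named genes and probe sets that passed, all kept their sign in every alternative run, which leaving out animals cannot change where the groups do not overlap, and 17 passed in all 10 fits without 1 animal. Of the other 17, Ankrd33b passed in 9 of the 10, Ctsc and Lgals3 in 7, Ttr in 4, Pcsk5, Kit and Ctss in 3, Serpinb9, Tcea3, Pdzk1 and Slc4a1 in 2, Fabp1 (without TG 661), Gpd1, Gamt, C1qa and Apob in 1 and Ptk2b in 0. Sign changed for 3 genes that did not pass. Fgfr1 was -0.052 in females alone and -0.0073 to 0.19 with 1 animal left out, -0.0013 without TG 614 and -0.0073 without WT 658. Egr1 was 0.36 with array weights, 0.39 with the actin covariate and 0.73 in males alone. Eif2s3y was 0.0058 with log2 of the linear value plus 16, 0.12 in males alone and -0.65 to 0.65 with 1 animal left out, positive without TG 614 (0.56), WT 618 (0.35), TG 652 (0.65), WT 658 (0.29) and WT 663 (0.40), as leaving out an animal shifts the sex ratio. Over all named genes, 1448 of 1784 values kept direction and side, 260 no longer passed, 63 passed in addition and 13 changed sign. Probe sets under the floor, Cyp27b1 among them, limit what signal over background can show.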

Other observations

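The tests of the clock genes were chosen after the pattern was seen.

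Clock genes set the animals numbered 612 to 619 apart from those numbered 650 to 663, in both genotypes. Dbp, a clock output gene, was higher by 2.57 in the lower number range (adjusted p = 0.00249). In the same model, which held genotype, sex and number range, 727 probe sets differed between the ranges. The actin control difference was 2.17 to 3.35 in the lower range and 1.82 to 2.42 in the higher. What part of these differences goes with RNA integrity was not tested. A phase score, the mean of 7 genes (Per1, Per2, Dbp, Tef, Nr1d1, Nr1d2 and Usp2) minus that of 3 of the opposite phase (Arntl, Clock and Nfil3), was 3.59 ± 0.23 (SD, n = 4) against 1.43 ± 0.75 (SD, n = 6), with exact two-sided permutation p = 0.0048, the smallest the 210 assignments can give. The first set was higher by 1.27 and the second differed by -0.89, which is consistent with collection at another time of day, although the sources give no times. Chip lot is not excluded, but the 1 animal of the first lot in the higher range, WT 650, scored 0.61, the lowest of all 10 and far from the 3.34 to 3.87 of the other first-lot animals, which runs against it. Between genotypes the score differed by 0.37 (exact two-sided permutation p = 0.603).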
